A study of Homo sapiens with 6 samples.

How the data were processed

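RNA of REH cells was measured in 6 libraries, 3 from cells given DMSO and 3 from cells given 25 µM ML141, each after 24 h. Groups and replicate numbers were taken from the sample titles, and the columns of the series' table were matched to samples through the sample descriptions. RNA was purified on columns and made into Illumina TruSeq RNA v2 libraries, per the labels' protocols; that kit enriches polyadenylated RNA and does not mark the strand.

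The deposited table holds whole-number counts per gene symbol, not normalized, in 1 column per library. Per the submitters' processing notes the tools were bcl2fastq 2.19, Trimmomatic, Bowtie2, Picard, featureCounts and DESeq2 and the genome build was hg38; their roles, settings, gene annotation and strand option are not given in the sources used here. Bowtie2 does not split reads across introns, so the reads counted over exon junctions depend on the reference it was given. Whether such a loss differed between the groups was not tested. The deposited table also holds scores, which are counts divided by 1 size factor per library (0.735 to 1.29) and rounded by the authors, and the log2 fold change, p-value and adjusted p-value of the authors' own comparison. The scores were not used for tests, and the authors' comparison was used only where it is named.

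The table has 26485 entries, of which 16703 had a count in some library. A total of 28 entries carry names in the form of dates, the result of a spreadsheet reading gene symbols as dates. They hold 0.362% of counts and stayed in the fit under the names given, 16 of them tested, with 2 names that occur more than once kept as separate entries. Of the gene names 93.8% matched a symbol in the reference tables. Mitochondrially encoded genes were not analysed here. Gene positions were taken from GENCODE release 29 on GRCh38, the same build as hg38, and 1-based. Replicates were compared before averaging: the chi-square per degree of freedom between libraries of a group was 2.97 to 19.6, so each pair differed by more than sampling noise and none was counted as a duplicate.

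Genes were kept with edgeR's filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 11454 genes with 99.9% of counts in each library after rounding. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest in R 4.3.3) on all 6 libraries with group as the only term, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM values use TMM-scaled library sizes, and levels are means ± SD of 3 libraries. In genes with few counts the ratio of summed counts over summed scaled library sizes is given with an exact Clopper-Pearson interval at 95%, which covers counting error only, since reads amplified by PCR are not independent molecules. Overlap with other genes was measured on the exons of the GENCODE basic annotation. Of CDC42 and the genes named by size or p, 27 in all, 9 shared exon bases with another gene. Of the overlapping genes named below, SOD2-OT1, PRAL and those with clone names such as AL031281.2 have no entry under that name in the deposited table.

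Before the data were examined, 37 gene lists were written down. The 30 with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, 2-sided, adjusted over the lists. For each list the number of changed genes is also given adjusted over the list alone. Some lists share genes, such as BTG2, SESN2 and KLF2, each of which is in more than 1 list. The rule for named genes, also written then, took CDC42, the 10 higher and 10 lower genes with the largest fold change among changed genes with a mean of at least 5 CPM, an official symbol and groups that did not overlap, and the 5 higher and 5 lower genes with the smallest p under the same conditions. It added the genes with the smallest p in each list, up to 4 in the direction of a list past camera and 2 against it, and up to 2 in other lists, which gave 127 genes, some of which are not reported here.

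Alternatives were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no or a stricter low-count filter (a mean count of 10 in each group and 1 CPM in 3 libraries), the DESeq2 Wald test (version 1.42.0), limma-voom, the replicate number as a block, each library or replicate number left out, a minimum fold change of 1.5, camera with an estimated correlation, fry, and a prior count of 0.5. Chosen after seeing the data were offsets that remove each library's trend on GC content and length of the longest transcript (loess, span 0.5), available for 97.8% of tested genes and for 100% of the genes in each list past camera, and upper-quartile factors and library totals for the lists.

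The tests were tested on simulated data for this comparison, with counts for 11454 genes drawn from the real means, library sizes and dispersions and 200 genes changed. The edgeR test recovered 61% of genes changed 1.5-fold and 85% of those changed 2-fold, with 15 false calls among 182 calls. Camera recovered a list of 30 genes shifted by 0.5 on the log2 scale and called 0 of 20 unchanged lists. Those genes were simulated as independent of each other. The 200 changed genes, equally many up and down, were far fewer than the 6230 called in the data. No GC trend or difference between replicate numbers was simulated. The simulation therefore does not show how TMM or the error rate behaves in such a setting. Figures were drawn with matplotlib 3.10.9.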

Results

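REH is an established human cell line grown from B-precursor acute lymphoblastic leukemia and carries the ETV6-RUNX1 gene fusion. Its RNA was sequenced after 24 h with 25 µM ML141, a small-molecule inhibitor of the GTPase CDC42, or with the solvent DMSO. There were 3 libraries per group, which the labels describe as coming from 3 independent experiments. The total counts of DMSO replicates 1, 2 and 3 were 8284299, 10319697 and 10837224, and those of ML141 replicates 1, 2 and 3 were 10436147, 12308039 and 10860349. At these depths 1 count stood for 0.0754 to 0.130 CPM (counts scaled to library size), and a gene with no count in a library could lie at up to 0.226 to 0.389 CPM, a limit of 3 counts that covers counting error only.

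The comparison addressed which transcripts change in REH cells given ML141. With ML141 all 38 tested genes of DNA replication and G1/S entry fell, with a median log2 fold change of -1.72 (camera adjusted p = 1.57e-15; adjusted p = 0.302 with an estimated correlation). Heat shock genes fell in 14 of 14 cases, with a median of -1.39 (camera adjusted p = 7.15e-09; adjusted p = 0.268 with an estimated correlation). Of the 33 tested genes of the ATF4 amino acid response 28 rose and 0 fell, with a median of 1.07 (camera adjusted p = 8.07e-11; adjusted p = 0.289 with an estimated correlation). By edgeR's quasi-likelihood test 6230 of the 11454 genes tested changed at an adjusted p of 0.05, which is 54.4% of them, and 3059 were higher and 3171 lower with ML141 (n = 3 per group). Among these, 774 were higher and 715 lower by more than 2-fold.

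The direction of small changes depended on scaling. With TMM factors 49.1% of the changed genes were higher, against 59.5% of 6454 with upper-quartile factors and 66.1% of 6796 with library totals, which moved the median log2 fold change of all genes up by 0.10 and 0.17. The libraries of the groups did not overlap in 7008 genes, or 61.2% of those tested, where chance gives 10%.

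CDC42 itself fell from 277.4 ± 2.50 to 201.5 ± 10.8 CPM (SD, n = 3), a log2 fold change of -0.46 (SE 0.075, edgeR adjusted p = 2.93e-04). The gene lies on chromosome 1 from 22052627 to 22092946 (hg38). Of its exon bases 62.6% are also annotated to AL031281.2 on the same strand, a gene with no entry under that name in the deposited table. An inhibitor of the protein need not act on the mRNA. Of the 37 tested genes encoding CDC42, related GTPases and their partners, 11 were higher and 11 lower, the same counts adjusted over the list alone, against 15 and 7 with library totals, and the list as a whole did not pass the camera test (adjusted p = 0.550). CDC42EP3, an effector that binds active CDC42, rose from 1.43 ± 0.13 to 17.8 ± 6.81 CPM, a log2 fold change of 3.61 (SE 0.329), and ARHGEF6, an exchange factor for RAC and CDC42, rose by 0.95 (SE 0.086).

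**Figure D1:**
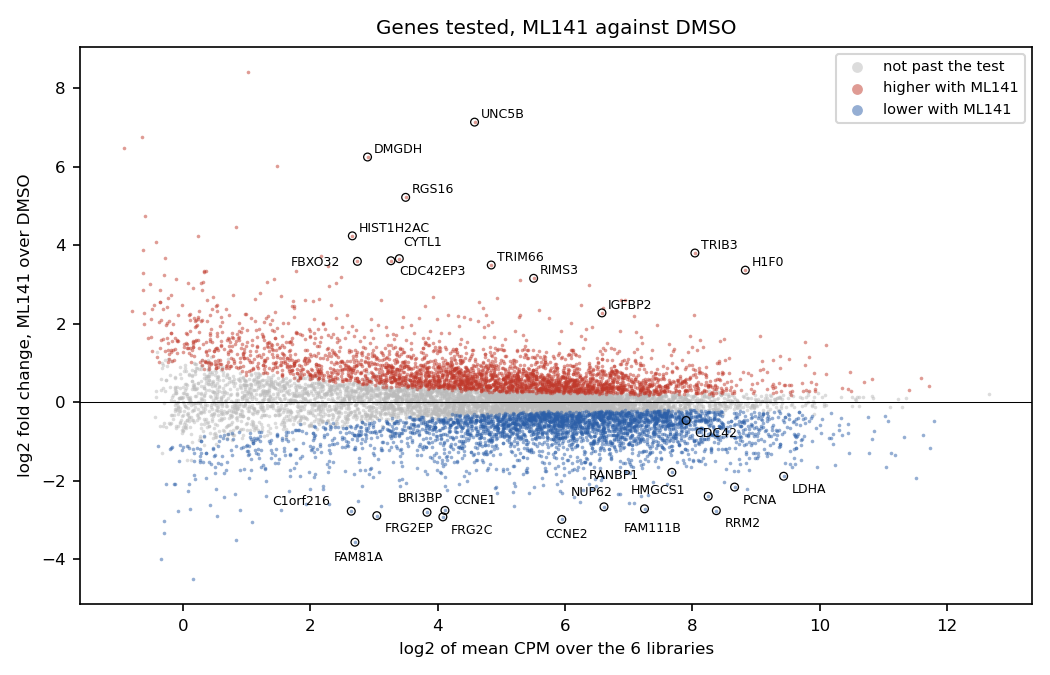
Log2 fold change of ML141 over DMSO (vertical axis) against log2 mean CPM over the 6 libraries (horizontal axis), with 1 point for each of the 11454 genes tested. Red and blue points are the 3059 higher and 3171 lower genes, grey points did not pass the test, and ringed points are CDC42 (-0.46) and the genes named by size of change or by p, from UNC5B at 7.14 to FAM81A at -3.56.

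Among genes with a mean of at least 5 CPM and groups that did not overlap, the largest rise was in UNC5B, a netrin receptor (chromosome 10, 71212570 to 71302864), from 0.33 ± 0.10 to 47.5 ± 9.34 CPM. It rests on 9 counts in the DMSO libraries together against 1674, a ratio of 145 with a 95% Clopper-Pearson counting interval of 76.0 to 317. DMGDH, the mitochondrial dimethylglycine dehydrogenase, had 5 counts against 517, a ratio of 80.4 (34.2 to 249). RGS16, a regulator of G protein signalling, had 16 against 780, a ratio of 37.9 (23.2 to 66.6). HIST1H2AC, a histone H2A gene, had 17 against 415, a ratio of 19.0 (11.7 to 32.9). The fitted log2 fold change of DMGDH was 6.25, against 7.04 without DMSO replicate 1 and 5.61 without DMSO replicate 3. That of HIST1H2AC was 4.24, against 4.85 without DMSO replicate 1. TRIB3, a pseudokinase induced by ATF4 (chromosome 20, 362835 to 397559), rose from 35.2 ± 3.43 to 491.7 ± 18.9 CPM, a log2 fold change of 3.80 (SE 0.096, edgeR adjusted p = 6.43e-10). H1F0, the linker histone H1.0 that accumulates in non-dividing cells, rose from 80.6 ± 7.40 to 832 ± 164 CPM, or 10.3-fold. CYTL1, FBXO32 (a ubiquitin ligase subunit controlled by FOXO factors) and TRIM66 rose by log2 3.66 (SE 0.328), 3.59 (SE 0.254) and 3.50 (SE 0.135). FBXO32 had 28 counts in DMSO against 435, a ratio of 12.1 (8.24 to 18.4). RIMS3, a regulator of synaptic exocytosis, rose 8.94-fold to 81.8 ± 0.16 CPM, and IGFBP2, which binds insulin-like growth factors, rose 4.85-fold to 158.7 ± 6.93 CPM.

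The largest falls included both E-type cyclins, which start DNA replication. CCNE2 fell from 109.9 ± 5.98 to 13.7 ± 6.66 CPM, 7.91-fold (edgeR adjusted p = 2.66e-06), and CCNE1 fell from 30.2 ± 1.67 to 4.39 ± 2.14 CPM, 6.74-fold. RRM2, the small subunit of ribonucleotide reductase, fell 6.77-fold from 579.9 ± 42.7 CPM, and FAM111B, a protease, fell 6.56-fold from 264 ± 7.10 CPM. NUP62, a protein of the nuclear pore, fell from 169 ± 26.2 to 26.7 ± 0.26 CPM, 6.33-fold. FAM81A fell by 3.56 on the log2 scale (SE 0.330), BRI3BP by 2.80 (SE 0.192) and C1orf216 by 2.77 (SE 0.235). FRG2C and FRG2EP fell by 2.92 (SE 0.197) and 2.89 (SE 0.214) on the log2 scale, but they belong to a family of near-identical copies, so which copy gave the reads is uncertain. Of the lower genes with the smallest p, HMGCS1 (chromosome 5, 43289395 to 43313512), the hydroxymethylglutaryl-CoA synthase of the cholesterol pathway, fell 5.26-fold from 511.7 ± 25.4 CPM. PCNA, the sliding clamp of DNA polymerases, fell 4.47-fold from 663 ± 44.5 CPM, LDHA, lactate dehydrogenase A, fell 3.69-fold from 1089.6 ± 57.6 CPM, and RANBP1, a regulator of nuclear transport, fell 3.44-fold from 317.7 ± 14.8 CPM. The library kit does not mark the strand, so reads from exon bases shared with another gene cannot be assigned by strand. Values are therefore less certain for CCNE2, of whose exon bases 47.5% overlap INTS8 on the opposite strand, for BRI3BP (29.7%, THRIL), RANBP1 (24.1%, TRMT2A), HMGCS1 (19.9%, AC114947.2) and NUP62 (11%, ATF5), and for RRM2, which shares 27.9% with AC007240.1 on its own strand.

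**Figure D2:**
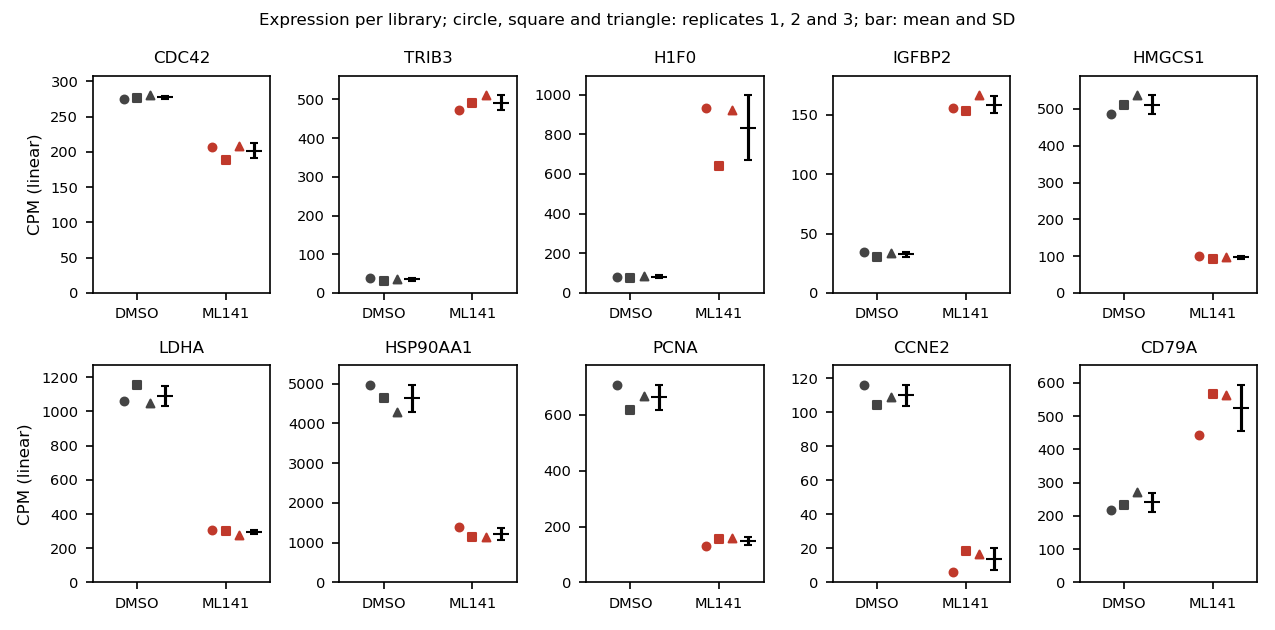
CPM (vertical axis, linear from 0) of 10 named genes in each library, with DMSO in grey and ML141 in red, circles, squares and triangles for replicates 1, 2 and 3, and bars for the mean and SD of 3 libraries. In each panel the groups do not overlap: CDC42 lies at 277.4 CPM in DMSO and 201.5 in ML141, TRIB3 at 35.2 and 491.7, and CCNE2 at 109.9 and 13.7.

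Genes of cell division were lower as a group. In the DNA replication and G1/S list, 38 of 38 tested genes fell, and 38 did so adjusted over the list alone (camera adjusted p = 1.57e-15; adjusted p = 0.302 with an estimated correlation). Besides PCNA and the E cyclins these included RRM1, the large subunit of ribonucleotide reductase, at a log2 fold change of -1.69 (SE 0.087), DTL, a substrate adaptor of a ubiquitin ligase acting in S phase, at -2.35 (SE 0.125), and SLBP, which binds histone mRNA, at -1.59 (SE 0.088). Relative to the DMSO mean, the mean log2 level of this list was -2.28 in ML141 replicate 1, against -1.60 and -1.66 in replicates 2 and 3. Of 31 genes of mitosis and G2/M, 29 fell, and 30 adjusted over the list alone, with a median of -0.97 (camera adjusted p = 6.55e-09; adjusted p = 0.403 with an estimated correlation). CCNA2, the A-type cyclin, fell to 111.8 ± 20.4 from 320 ± 31.5 CPM, BUB1B of the spindle checkpoint by 1.27 on the log2 scale (SE 0.107), ANLN, needed for cytokinesis, by 1.32 (SE 0.123) and CKAP2 by 0.97 (SE 0.095). Per library, the replication list minus the mitosis list was -0.36 ± 0.15 in DMSO and -1.28 ± 0.43 in ML141 on the log2 scale, with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. Of 7 tested replication-dependent histone genes, 3 were higher and 0 lower, and the same adjusted over the list alone; HIST2H2BE rose 4.47-fold, and the list did not pass camera (adjusted p = 0.227). Most mRNA of these genes ends without a poly(A) tail, so a library of polyadenylated RNA holds part of it.

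Genes of ribosome assembly and MYC regulation fell in 31 of 32 cases, and in 31 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 3.07e-10; adjusted p = 0.268 with an estimated correlation). NOLC1 and NCL, abundant nucleolar proteins, fell 2.69-fold and 2.43-fold, the latter from 3168 ± 107 CPM, and LYAR and the polyamine enzyme ODC1 fell 2.25-fold and 1.98-fold. Of 48 cytosolic ribosomal protein genes, 12 were higher and 4 lower, and the same adjusted over the list alone, with RPL13 at 0.49 (SE 0.084) and RPL14 at -0.39 (SE 0.074). With library totals 30 of them were higher and 2 lower, and the list did not pass camera (adjusted p = 0.222).

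Metabolic genes fell across several pathways. In cholesterol biosynthesis 20 of 23 tested genes fell, 20 also adjusted over the list alone, where 1 more was higher, with a median of -1.27 (camera adjusted p = 6.55e-09; adjusted p = 0.268 with an estimated correlation). ACAT2 fell 4.74-fold, SQLE, the squalene epoxidase, 3.18-fold and FDPS, the farnesyl diphosphate synthase, 2.86-fold. Exon overlap with a gene on the opposite strand makes the values of ACAT2 (34.8%, SOD2, and 45.8%, SOD2-OT1), FDPS (28.9%, RUSC1-AS1) and LPCAT3 (66.4%, EMG1) less certain. In fatty acid synthesis 8 of 11 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.00317; adjusted p = 0.268 with an estimated correlation). The elongase ELOVL6 fell 4.70-fold, the desaturases FADS2 and FADS1 fell 2.28-fold and 1.98-fold, ACLY, which makes cytosolic acetyl-CoA, fell 2.10-fold, and LPIN1, a phosphatidate phosphatase, rose 1.77-fold. Of 5 LXR targets, 2 were higher and 1 lower, the same adjusted over the list alone, with ABCA1, a cholesterol exporter, up 1.87-fold and LPCAT3 down 1.81-fold (camera adjusted p = 0.550).

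In glycolysis 16 of 19 genes fell and 1 rose, the same adjusted over the list alone, with a median of -0.93 (camera adjusted p = 3.98e-06; adjusted p = 0.292 with an estimated correlation). ENO1, enolase, fell 3.03-fold from 1815 ± 43.9 CPM, PKM, pyruvate kinase, 3.11-fold and TPI1, triosephosphate isomerase, 2.77-fold, while the glucose transporter gene SLC2A3 rose 1.63-fold. Of 42 nuclear genes of oxidative phosphorylation 38 fell (27 with library totals), and 39 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 3.03e-09; adjusted p = 0.268 with an estimated correlation). They included ATP5G1, ATP5G3, NDUFS5 and COX7B, at -1.79 (SE 0.117), -1.10 (SE 0.078), -1.21 (SE 0.088) and -1.22 (SE 0.098). Hypoxia targets went both ways, with 8 of 18 higher and 4 lower, or 8 and 6 adjusted over the list alone. NDRG1 rose 4.69-fold, FAM162A fell 1.94-fold, and the list did not pass camera (adjusted p = 0.387).

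Stress pathways moved in opposite directions. Of the 33 tested genes of the ATF4 and amino acid response 28 rose and 0 fell, with 29 higher adjusted over the list alone (camera adjusted p = 8.07e-11; adjusted p = 0.289 with an estimated correlation). PPP1R15A, which restores translation after stress, rose 7.98-fold, SESN2, a stress-induced inhibitor of mTORC1, 4.05-fold and WARS, the tryptophanyl-tRNA synthetase, 3.23-fold. Heat shock genes fell in 14 of 14 cases, and in 14 adjusted over the list alone, with a median of -1.39 (camera adjusted p = 7.15e-09; adjusted p = 0.268 with an estimated correlation). HSP90AA1 fell from 4635.9 ± 338.8 to 1219 ± 149 CPM and HSPA8 from 3210.7 ± 160.7 to 1021 ± 4.60 CPM. The mitochondrial chaperonin genes HSPD1 and HSPE1 fell 2.99-fold and 4.36-fold. HSPE1 shares 18.6% of its exon bases with HSPE1-MOB4 on its own strand and 16.4% with HSPD1 on the other. Of 24 genes for chaperones and folding control of the endoplasmic reticulum 10 were higher and 7 lower, the same adjusted over the list alone, against 12 and 3 with library totals (camera adjusted p = 0.446). HERPUD1, which acts in degradation of misfolded proteins, rose 4.58-fold and the chaperone CALR fell 2.46-fold, where 14.2% of exon bases overlap AC092069.1 on the opposite strand. The mean of this list was 0.27 on the log2 scale, whereas its median was below 0 with TMM and 0.17 with library totals.

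Of 26 p53 targets 12 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.577 with an estimated correlation). The median was 0.20 and the mean 0.53 on the log2 scale, so the mean rested on part of the genes. SESN2, up 4.05-fold, is in this list and in the ATF4 list. BBC3, the pro-apoptotic BH3 protein PUMA, rose 6.07-fold, BTG2 3.52-fold and the death receptor gene TNFRSF10B 2.40-fold, while DDB2 and POLH, both of the DNA damage response, fell 1.51-fold and 1.37-fold. The call was lost without ML141 replicate 1 (adjusted p = 0.0984), the library in which the list mean was 0.70 above DMSO, against 0.40 and 0.45 in ML141 replicates 2 and 3, and with library totals (adjusted p = 0.0521). In the BCL2 family 7 of 15 were higher and 4 lower, the same adjusted over the list alone, with BMF up 5.59-fold and no camera call (adjusted p = 0.279). Of 16 NRF2 targets 4 were higher and 8 lower, or 4 and 9 adjusted over the list alone, with PRDX1, of whose exon bases 30.3% overlap MMACHC on the opposite strand, down 2.93-fold and PGD down 1.75-fold (camera adjusted p = 0.127). Fewer than 5 genes were tested for the aryl hydrocarbon receptor targets, where 1 of 4 was higher and 2 lower, or 2 and 2 adjusted over the list alone and 2 and 1 with library totals, and for metallothioneins and zinc genes, where 0 of 4 were higher and 2 lower, the same adjusted over the list alone, against 0 and 1 with library totals. NQO1 rose 1.89-fold (18.4% overlap with AC092115.2 on the opposite strand) and MT2A fell 2.16-fold. CYP1A1 fell 2.25-fold, a call lost without DMSO replicate 2 (adjusted p = 0.0524). MT1X, at -0.45 (SE 0.168), was not past the test with upper-quartile factors (adjusted p = 0.121), with library totals (0.198), or without DMSO replicate 2 (0.138), DMSO replicate 3 (0.173) or ML141 replicate 3 (0.143), and 39% of its exon bases overlap AC026461.1 on its own strand.

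**Figure D3:**
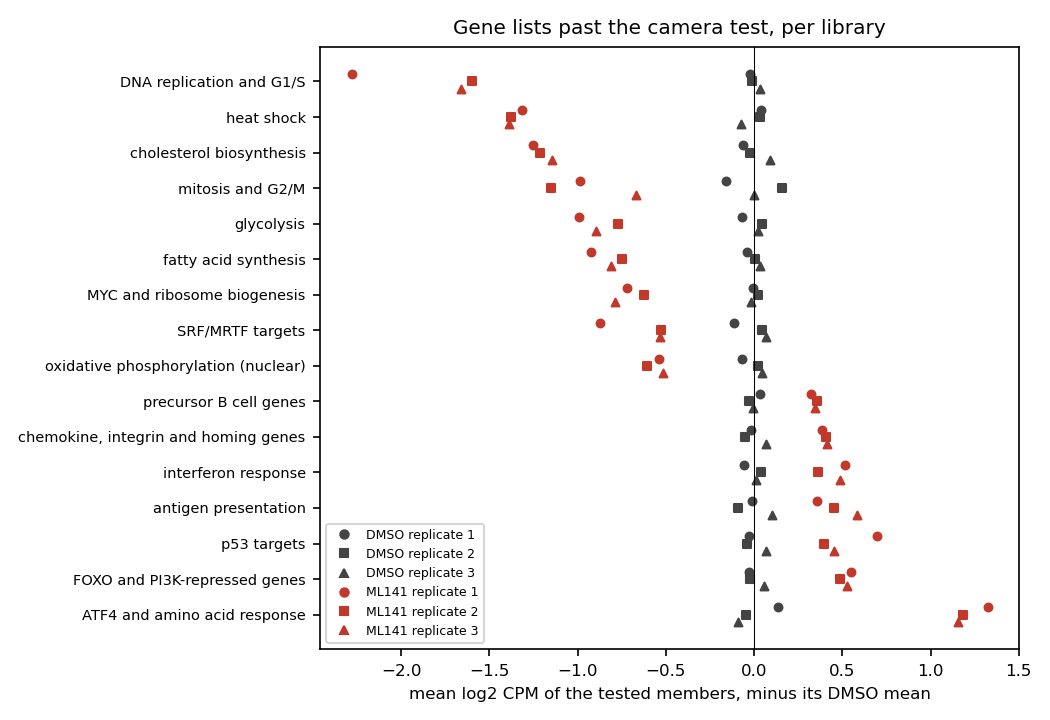
Mean log2 CPM of the tested genes of each list, minus the DMSO mean of that list (horizontal axis), for the 16 lists past the camera test (vertical axis). Grey and red points are DMSO and ML141 libraries, with circles, squares and triangles for replicates 1, 2 and 3. In the DNA replication and G1/S list ML141 replicate 1 lies at -2.28 and the other ML141 libraries at -1.60 and -1.66.

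Precursor B cell genes rose in 16 of 26 cases and fell in 2, or 18 and 3 adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.0113; adjusted p = 0.290 with an estimated correlation). CD79A, a signalling chain of the B cell receptor, rose from 240 ± 27.3 to 524.9 ± 69.6 CPM, the B lineage factor PAX5 rose 1.67-fold and POU2AF1, a coactivator of octamer-binding factors in B cells, 1.65-fold. CD9 rose from 28 to 198 counts, a ratio of 5.50 with a counting interval of 3.69 to 8.48, while the lymphoid factor IKZF1 fell 1.84-fold and CD24 fell 1.39-fold. Of 8 mature B and plasma cell genes 3 were higher and 4 lower, or 4 and 4 adjusted over the list alone. PRDM1, which drives plasma cell fate, had 10 counts in DMSO against 80, a ratio of 6.22 (3.21 to 13.5). CD83 was 3.30-fold lower, and the list did not pass camera (adjusted p = 0.937). Of 18 genes linked to ETV6-RUNX1 leukemia 7 were higher and 3 lower, the same adjusted over the list alone, against 11 and 3 with library totals (camera adjusted p = 0.127). ETV6 was up 3.26-fold, but REH carries the ETV6-RUNX1 fusion, and counts per gene do not separate ETV6 from fusion transcripts.

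FOXO targets and genes repressed by PI3K rose in 11 of 17 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0160; adjusted p = 0.268 with an estimated correlation). TXNIP, an inhibitor of thioredoxin and glucose uptake, rose 3.54-fold, KLF2, a quiescence factor of lymphocytes, 5.94-fold and IRS2 2.44-fold. CCNG2 rose 1.71-fold, and TRIB1 and BCL6 fell 3.48-fold and 1.46-fold. Interferon response genes rose in 14 of 26 cases and fell in 3, or 17 and 3 adjusted over the list alone (camera adjusted p = 0.0160; adjusted p = 0.268 with an estimated correlation). IFIT2 rose 3.27-fold, RSAD2 2.62-fold, XAF1 1.79-fold (69.9% overlap with PRAL on the opposite strand) and MX2 1.75-fold, while OAS3 fell 2.13-fold and BST2 1.68-fold. Of 11 antigen presentation genes 7 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0253; adjusted p = 0.403 with an estimated correlation), a call that was lost without DMSO replicate 2 (adjusted p = 0.0640), without the low-count filter (adjusted p = 0.0687) and with library totals (adjusted p = 0.0521). HLA-C rose 1.72-fold, HLA-B 1.64-fold and the invariant chain gene CD74 1.64-fold from 834.7 ± 61.5 CPM. HLA-C and HLA-B resemble each other closely, so the split of reads between them is uncertain, and 23.5% of the exon bases of HLA-B overlap AL671883.2 on the opposite strand.

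Genes controlled by the actin-sensing SRF/MRTF pathway fell in 14 of 19 cases and rose in 1, or 15 and 1 adjusted over the list alone (camera adjusted p = 1.68e-04; adjusted p = 0.375 with an estimated correlation). LIMA1, CFL1, WDR1 and TPM4, all actin-binding proteins, fell 2.65-fold, 2.45-fold, 1.78-fold and 1.52-fold, and MYH9, the heavy chain of nonmuscle myosin, rose 1.23-fold, a call lost without DMSO replicate 1 (adjusted p = 0.0689). Of the exon bases of TPM4 19.3% overlap AC008894.3 on the opposite strand. Relative to DMSO the list mean was -0.87 in ML141 replicate 1 and -0.53 in both other ML141 libraries. Chemokine, integrin and homing genes rose in 9 of 19 cases and fell in 2, the same adjusted over the list alone, against 13 and 0 with library totals (camera adjusted p = 0.0253; adjusted p = 0.268 with an estimated correlation). ITGA5 rose 2.14-fold, ICAM2 2.13-fold (42.6% overlap with PRR29 on the opposite strand), FERMT3, which activates integrins, 1.94-fold and RAPGEF1 1.51-fold, while RAP1A fell 1.30-fold and the kinase gene PTK2B 1.26-fold. Neither passed the test with library totals (adjusted p = 0.0667 and 0.232), and PTK2B did not without DMSO replicate 3 (0.0683) or with upper-quartile factors (0.109).

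The remaining signalling lists did not pass camera. Of 17 immediate early genes 10 were higher and 2 lower, of 13 NF-kB targets 5 and 3, of 22 lysosome and autophagy genes 8 and 3, and of 8 MAPK feedback genes 2 and 3, in each case the same counts adjusted over the list alone, with camera adjusted p of 0.0781, 0.844, 0.127 and 0.916. The MAPK feedback list had a median of 0.17 and a mean of -0.05 on the log2 scale, and with library totals 5 of its genes were higher and 1 lower. With library totals 13 lysosome and autophagy genes were higher and 2 lower. TNFAIP3, an inhibitor of NF-kB, fell 1.59-fold, the autophagy gene MAP1LC3B and the lysosomal protease gene CTSD rose 2.57-fold and 1.74-fold, ETV4 fell 1.64-fold and DUSP6 rose 1.25-fold, a call lost without DMSO replicate 2 or DMSO replicate 3 (adjusted p = 0.0578 in both cases). Overlap makes the values of CTSD (54.9% with AC068580.4 on its own strand) and DUSP6 (39.4% with AC024909.2 on the opposite strand) less certain.

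Markers of other cell types were near the limit of detection, with exceptions. The T and NK cell list had 1 tested gene and the stromal and epithelial list 2, of which 0 changed, also adjusted over the list alone. CD3D, CD2 and EPCAM had 0 counts in all libraries. Of 4 tested myeloid markers and 2 tested erythroid and megakaryocyte markers 0 were higher and 1 in each was lower, the same adjusted over the list alone; with library totals 1 erythroid and megakaryocyte marker was higher. MPO fell from 41.4 ± 0.36 to 26.2 ± 1.38 CPM and TFRC, the transferrin receptor of dividing cells, from 729.2 ± 60.3 to 220 ± 9.35 CPM, while PDGFRB was at 41.3 and 35.7 CPM in DMSO and ML141 without passing the test.

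Of the 37 lists 30 had at least 5 tested genes, and 16 passed the camera test with its preset correlation, 7 up and 9 down, against 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05, and 21 by fry, which include the 16. Another split of the 6 libraries also gave 16 lists, and the 9 splits other than DMSO against ML141 gave at most 0 changed genes. Each of those 9 mixes both treatments unequally, so it holds part of the ML141 difference and does not measure what chance alone gives. These counts therefore cannot decide whether the list or gene calls arise by chance. The authors' deposited table gave 5821 changed genes, 2751 higher and 3070 lower, and 5741 of these were also called here, all in the same direction.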

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

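All settings were planned before the data were examined except the GC and length offsets and, for the gene lists, upper-quartile factors and library totals. The number of changed genes was 6230 and went from 4161 to 6567 when libraries were left out, lowest without both libraries numbered 3, and from 5617 to 7362 over the other settings except 1: with a minimum fold change of 1.5 it was 1811 (813 higher, 998 lower), since that test no longer counts smaller changes. CDC42 stayed lower and past the threshold in 20 of 20 alternatives, from -0.49 to -0.29 on the log2 scale, with adjusted p up to 0.0116. Of 2533 pairs of a named gene and an alternative, 2510 kept the direction and the side of the threshold, 0 reversed and 23 lost the call, from MYH9, DUSP6, CYP1A1, MT1X, RAP1A and PTK2B; the cause was not tested. Their adjusted p ranged from 7.88e-04 to 0.0909, 1.95e-04 to 0.0836, 0.00181 to 0.0883, 0.00134 to 0.402, 4.41e-04 to 0.0667 and 2.97e-05 to 0.232. All named genes but CDC42 were picked by fold change or p in these same data, so these pairs say little of other genes. Of all 6230 called genes, 6206 were also called with DESeq2 size factors, 5670 with upper-quartile factors and 5361 with library totals. Without both libraries numbered 3 the number was 4126.

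The number of lists past camera was 16 and went from 15 to 17 when libraries were left out. Over the other settings except 1, with fry among them, the number of lists called went from 15 to 21. The exception was camera with a correlation estimated from the data, which called 0 (lowest adjusted p = 0.268, with 5 lists at an unadjusted p under 0.05). Fry, which tests a list against no change and not against the other genes, gave 21. No list reversed. The p53 and antigen presentation lists were the only ones of the 16 to lose the call elsewhere. For p53 targets camera adjusted p was 0.0984 without ML141 replicate 1, 0.119 without both libraries numbered 1 and 0.0521 with library totals. For antigen presentation it was 0.0640 without DMSO replicate 2, 0.0687 without the low-count filter and 0.0521 with library totals. Over the alternatives adjusted p ranged from 0.00986 to 0.577 for p53 targets and from 0.00757 to 0.403 for antigen presentation. In both lists the lowest value came from fry and the highest from camera with an estimated correlation. The cause was not tested.

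The replicate number was not treated as pairing, because the labels do not say that a number marks a shared experiment, although the sample descriptions give same-numbered libraries a tag in common whose meaning is not stated, and the deviations from the group means correlated across genes by 0.37, 0.08 and 0.18 for numbers 1, 2 and 3. DMSO replicate 3 correlated best with ML141 replicate 2 (0.29). With GC and length offsets the correlations for numbers 1, 2 and 3 were 0.25, 0.09 and 0.18, and those of unlike numbers are not given. With the replicate block edgeR called 6979 genes and 17 lists, DESeq2 5617 genes, without CYP1A1 (adjusted p = 0.0615) and MT1X (0.0549), and edgeR with GC and length offsets 7362 genes, against 6902 with the offsets alone. Leaving out mitochondrially encoded genes was not run, since no entry of the table used carried such a name. Depth limits the low end: at 8284299 to 12308039 counts per library, ratios such as those of UNC5B and DMGDH rest on 9 and 5 counts in DMSO.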

Other observations

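Chosen after the results were seen were the gene lists and genes named first, and the tests of library scaling, of a larger response in ML141 replicate 1 and of a difference shared with DMSO replicate 1. Those lists were picked because of their values, so no test of them as lists is given. The GC and length offsets used below were also not planned before the data were examined. Splicing factors fell in 27 of 28 cases, with a median log2 fold change of -0.84, SRSF7 by 1.42 on the log2 scale (SE 0.073) and SRSF1 by 1.47 (SE 0.079). Importins, exportins and the Ran cycle fell in 22 of 24 cases, with a median of -0.67, including CSE1L, the exporter of importin alpha, by 1.76. All 8 tested subunits of the CCT chaperonin, which folds actin and tubulin, fell, with a median of -0.86. Lower were also 27 of 30 proteasome genes, with a median of -0.47, and 13 of 15 enzymes of purine and pyrimidine synthesis, with a median of -0.65, PAICS by 1.57.

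Of 17 genes that restrain growth or are high in resting cells, 13 rose and 0 fell, with a median of 1.18, including TSC22D3 at 2.60 (SE 0.109), YPEL3 at 2.24 (SE 0.133) and YPEL5 at 2.15 (SE 0.130). TXNIP, BTG2 and CCNG2 are shared with lists fixed earlier. Host RNAs of snoRNAs went both ways, with 8 of 19 higher and 5 lower; ZFAS1 rose by 2.22 (SE 0.149) and GAS5 by 1.60 (SE 0.128). Of 9 tested entries named Sep with a number, 2 were higher and 6 lower: Sep-09 rose 2.17-fold to 1008.6 ± 19.5 CPM, while Sep-11 fell 1.93-fold and Sep-03 fell 2.34-fold. With library totals the log2 fold changes of Sep-02, Sep-06 and Sep-07 were -0.22, -0.04 and -0.13, against -0.40, -0.22 and -0.30 with TMM. Those of Sep-03, Sep-08 and Sep-11 were -1.05, -0.44 and -0.78 with library totals, and those of Sep-01 and Sep-09 were 0.97 and 1.29. Names of this form, except Sep-15, are the spreadsheet form of septin gene symbols, and septins bind CDC42 effectors. The entries are given here only as named.

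For the fall of the DNA replication and G1/S genes, the list median was -1.54 and its upper quartile -1.31 with library totals. Library totals moved genes by a median of only 0.17 from TMM, so this result was nearly fixed beforehand. It shows that the choice between these scalings is not the whole cause, and it cannot test an error that they share. With offsets for GC content and gene length the median was -1.67 and the upper quartile -1.53, so that trend does not account for all of it either. A response of the cells to ML141, the difference that the design names, stays open, and the RNA alone does not separate fewer cells in S phase from lower transcription per cell. The replication list minus the mitosis list differed by -0.91 between the groups, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give.

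The rise of the ATF4 response genes kept a median of at least 1.07 under 3 other scalings, with a lower quartile of 0.35. Those scalings left the median gene in place or moved it up from TMM, by up to 0.17. They could therefore not have lowered the rise, and they cannot decide on library scaling. With GC and length offsets the median was 1.05 and the lower quartile 0.40, so those trends do not account for all of it. A response of the cells to ML141 stays open, and 1 compound at 1 dose does not separate effects through CDC42 from others. No biological explanation was tested.

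ML141 replicate 1 differed from replicates 2 and 3 by a chi-square per degree of freedom of 19.6 and 9.83. Replicates 2 and 3 differed by 7.38, so replicate 3 lay between the others. Across 11204 genes the difference of ML141 replicate 1 from the mean of replicates 2 and 3 had a Spearman rho of -0.53 with GC content and 0.03 with length. Genes of the highest GC content (limit 61.1%) had a median relative log2 level of -0.15, 0.27 and 0.07 in ML141 replicates 1, 2 and 3. The rho with GC therefore reflects replicate 2 as well as replicate 1. DMSO replicate 1 differed from the other DMSO libraries in a like way (rho with GC -0.44), with a rho of 0.42 between both differences across 11454 genes. Genes are not independent replicates. With GC and length offsets that rho was 0.26, so a part of the shared difference remained. A technical or handling difference of the libraries numbered 1 could give this shared part. They share a tag in the sample descriptions whose meaning is not stated, and without both of them edgeR called 6461 genes. In the SRF/MRTF list DMSO replicate 1 was also lower, at -0.11 against 0.05 and 0.07 in DMSO replicates 2 and 3. In the DNA replication and G1/S list it was not set apart, at -0.03 against -0.01 and 0.04, whereas ML141 replicate 1 lay at -2.28 against -1.60 and -1.66. A larger response in ML141 replicate 1 cannot be told apart from such a difference. ML141 replicate 1 minus replicate 2 had a rho of 0.12 with ML141 replicate 3 minus DMSO, between the bounds set for the test. That rho also carries the GC deviation of replicate 2.

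Chance as the source of the group difference was examined with the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 6230 genes and the highest of the others 0, so 1 of 10 splits gave as many. For the lists the real split gave 16 and the highest of the others 16, so 2 of 10 splits gave as many. That other split set DMSO replicate 1 with ML141 replicates 1 and 3. All splits but the real one mix both treatments unequally. They keep part of the ML141 difference between their groups and put the rest within them. Their counts of genes and lists therefore cannot decide on chance.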
